A study of Mus musculus with 2 samples.

How the data were processed

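The series holds 2 RNA-seq libraries of mouse Treg cells sorted as CD4+ YFP+ from lymph nodes and spleen, each from cells pooled from 5 to 10 mice of 5 weeks. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was captured on oligo-dT beads, and libraries were made with a transposase-based kit from 1 ng of DNA. Per the submitters' processing notes, TopHat2 2.0.3, HTSeq and the genome build mm10 were used. The gene annotation, the strand setting of the counting and the read length are not given in the sources used here. The authors deposited a single table of raw read counts per gene for both libraries, with whole numbers that were not normalized. It held 24086 entries, of which 5 are the counter's own categories for reads outside genes and 24081 are gene symbols.

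Samples were grouped by title, WT and KO. The genotype label reads wild type for both samples, so the grouping rests on the titles, together with the series' design text, which names a control with 1 floxed allele of the targeted gene and a knockout with both alleles floxed. The 2 columns of the table carry these titles.

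Of all counted entries, 76.6% were assigned to genes in each library (11662867 of 15230392 in WT, 23789264 of 31039011 in KO). The shares outside genes were left out of library sizes: reads aligned to several places (15.6% in WT, 15.0% in KO), reads outside annotated exons (6.26% and 6.81%) and reads shared between genes (1.53% and 1.57%). Reads of low alignment quality and unaligned reads are listed at 0 in both. The 10 most counted genes took 5.57% and 5.50% of gene reads, and 14093 and 14838 genes had at least 1 read. Reads that align to several places are not counted to genes, so genes with near-identical copies are undercounted and uncertain. The kit does not mark molecules with identifiers, as far as the labels say, so reads are not independent molecules.

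The counts were scaled with the TMM factors of edgeR 4.0.16 in R 4.3.3 (1.03 for WT, 0.974 for KO), brought to the mean effective library size, and given a pseudocount of 1. The log2 ratio of KO over WT was computed for each gene with a mean of at least 20 raw counts over both libraries (10899 genes, called expressed). An exact conditional binomial (Clopper-Pearson) interval at 95% was computed from the raw counts for each ratio. It covers counting error only, holds no spread between mice, and uses no pseudocount. It treats reads as independent, so it can be too narrow even for counting error. The folds printed for single genes are ratios of the scaled counts without the pseudocount, to match the interval, so the log2 ratios understate them for genes with few reads. A gene was called higher or lower at 2-fold or more, and list members were called at 1.5-fold or more, both on the log2 ratio with the pseudocount. With 1 library per group no test was run and no p-value was made; edgeR and DESeq2 1.42.0 gave scaling factors only. Across expressed genes the Spearman correlation of the libraries was 0.985, the median log2 ratio 0.01 and its SD 0.46. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.

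The groups, the scaling, the floors, the thresholds, the gene lists and the rule for named genes were fixed before the data were examined. The rule names the targeted gene, the 12 genes with the highest and the 12 with the lowest ratio among genes with a mean of at least 100 counts, leaving out predicted genes, antigen receptor segments and pseudogene symbols. From each list it names up to 4 measured members with the largest absolute ratio, and always Foxp3, Il2ra, Ctla4, Irf4, Il10, Icos, Klrg1, Ccr7, Mki67 and Cdkn1a. Some genes that the rule takes, the targeted gene among them, are not reported here. Genes of the marker lists are given as levels or read counts, and 2 erythroid genes, picked after seeing the data, also as folds. The 20 lists were Treg identity, effector Treg, resting T cell, TCR and immediate early, TCR signalling machinery, S phase, G2 and mitosis, SUMO pathway, p53 targets, apoptosis regulators, interferon-stimulated, effector cytokines and helper factors, chemokine receptors and adhesion, glycolysis, oxidative phosphorylation, cholesterol synthesis, amino acid uptake and mTORC1, unfolded protein and heat shock, cytoplasmic ribosomal proteins, and germline genes. The 15 marker lists covered B cells, plasma cells, CD8 T cells, NK cells, monocytes and macrophages, neutrophils, dendritic cells, mast cells and basophils, erythroid cells, platelets, stromal and endothelial cells, thymocytes, gamma delta and innate-like T cells, sex-linked genes and mitochondrially encoded genes.

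For each list with at least 3 measured members, the median log2 ratio was placed as a percentile among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. A list was said to stand apart outside the central 95%. This describes these 2 libraries and says nothing of replication, since genes are not replicates.

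Gene coordinates, GC content and transcript length came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. A GC content and length were found for 10851 of the 10899 expressed genes (99.6%). Exon overlaps between named genes and other genes came from the same annotation. They are printed for some genes only. Others have them too, such as Hif1a with Gm49321 on the same strand, and Cxcl10 with Art3 and Ube2c with Tnnc2 on the opposite strand.

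The steps were tested on simulated counts drawn from the real means and depths. For KO against WT over 10910 genes, all simulated changes of 2 and -2 on the log2 scale were called at 2-fold, as were 100% of those of 1.32 and 96.0% of those of -1.32, with 0.0746% of unchanged genes called. The counting interval held the true ratio for 95.7% of genes, and 3.00% of 200 random lists stood apart. The simulated counts held Poisson counting error only, with no spread between mice, pools or library preparations. These rates therefore check the steps and are not rates of false calls between 2 real pools.

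Alternatives were other scalings (total counts, DESeq2 size factors), pseudocounts of 0.1 and 5, no floor or a floor 5 times as high, thresholds of 1.5-fold and 4-fold, the counting interval as a condition, 10 expression bins or no matching, the mean of a list, and lists without shared genes. Removal of a smooth trend on GC content and length, and thinning of the KO library to the WT total, were added after seeing the data.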

Results

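RNA was sequenced from regulatory T cells (Treg cells, the CD4+ T cells that carry the transcription factor Foxp3 and restrain immune responses) of 5-week-old C57BL/6 mice. The cells were sorted as CD4+ YFP+ from lymph nodes and spleen, YFP marking cells in which the Foxp3-driven Cre recombinase was expressed. The study asks whether Treg expansion and function need SUMOylation, the attachment of small SUMO proteins to other proteins, and targets a gene of that pathway with the Cre recombinase. The control library (WT) came from mice with 1 floxed allele of the targeted gene and the knockout library (KO) from mice with both alleles floxed. Each library was made from cells pooled from 5 to 10 mice, and there was 1 library per group, so no difference below has a replicate check and no p-value was computed. The WT library held 11662867 reads assigned to genes and the KO library 23789264. The intervals given are exact 95% intervals for counting error only. Folds of single genes and intervals use no pseudocount; log2 ratios, calls and list medians use a pseudocount of 1, which makes the ratios of genes with few reads smaller.

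The libraries are told apart by the titles of the samples. The genotype label reads wild type for both, so directions below rest on those titles.

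The KO library had far less RNA of genes that mark effector Treg cells, the activated subset that homes to tissues. The chemokine receptors Cxcr3 and Ccr4 were 16.5-fold (interval 12.7 to 21.7) and 11.5-fold lower, the inhibitory receptor Tigit 11.5-fold lower, and the IL-33 receptor Il1rl1 7.93-fold lower. Genes of resting, recirculating T cells, immediate early and T cell receptor response genes, and genes of cholesterol synthesis were higher as groups by smaller amounts. Their list medians were 0.34, 0.38 and 0.38 on the log2 scale, and not every member was higher. Foxp3 was 1.85-fold higher (1.81 to 1.90), and the proliferation marker Mki67 did not differ detectably at this depth (1.02-fold, 0.927 to 1.12). Among 10899 expressed genes, 173 were at least 2-fold higher in the KO library and 227 at least 2-fold lower.

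**Figure D1:**
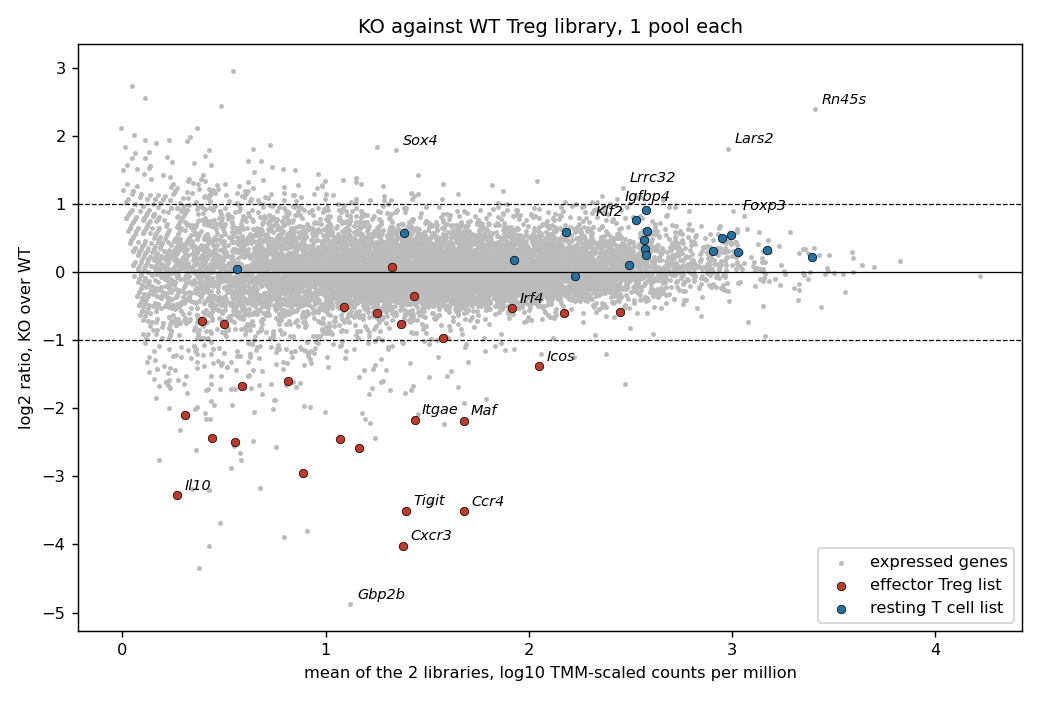
The log2 ratio of the KO to the WT library (vertical axis) against the mean level of the gene, in log10 of TMM-scaled CPM (horizontal axis), for 10899 expressed genes. Red points are the 26 measured effector Treg genes, of which 21 were at least 1.5-fold lower in the KO library; blue points are the 18 resting T cell genes, of which 17 lay above 0. Dashed lines mark 2-fold differences.

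The ratio moved with the GC content of the transcript. Across genes, which are not independent replicates, its Spearman correlation with GC content was 0.43, and the median log2 ratio ran from -0.19 in the tenth of genes with the lowest GC content to 0.37 in the tenth with the highest. Genes at least 2-fold higher had a median GC content of 56.0%, against 48.4% for those at least 2-fold lower and 49.9% for all. A smooth trend on GC content and length was then removed, a step chosen after seeing the data. Below it is called the GC correction, or removal of the GC trend, and always covers length as well. With it, 99 genes were at least 2-fold higher and 239 lower. Of the 2-fold genes 29.3% were then higher, compared with 43.25% as scaled. The list medians for resting T cell, TCR and immediate early, and cholesterol synthesis genes were then 0.37, 0.28 and 0.39, still outside the central 95% of their random lists, and that of oxidative phosphorylation was 0.04.

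Of the 26 measured genes of the effector Treg list, 21 were at least 1.5-fold lower in the KO library, 5 lay between and none was higher. The list median was -1.64, below all of the 10000 random lists of equal size drawn from genes of like expression, whose central 95% ran from -0.16 to 0.18. The differences were large for receptors: Ccr4 went from 1058 reads in the WT library to 178 in the KO library, Cxcr3 from 546 to 64, Tigit from 548 to 92, and Ccr2, a receptor for inflammatory chemokines, from 238 to 83 (5.54-fold lower). The costimulatory receptor Icos had 1945 and 1441 reads, 2.61-fold lower (2.44 to 2.80). The suppressive cytokine Il10 had 41 and 7 reads, 11.3-fold lower with a wide interval of 5.03 to 29.9, and Klrg1, a marker of terminally differentiated effector Treg cells, had 40 and 17 (4.55-fold lower, 2.52 to 8.56). The secreted suppressive protein Fgl2 was 6.04-fold lower. The transcription factor Irf4, which effector Treg cells need, differed less, at 1.44-fold lower (1.34 to 1.56). With the GC correction 21 genes of the list were again at least 1.5-fold lower, 19 of them the same. Among markers of other cells, the CD8 T cell and NK cell lists had medians of -0.34 and -0.24. Both lay inside the central 95% of their random lists, which was wide (-0.47 to 0.51 and -0.47 to 0.49). The 2 measured erythroid genes were lower too, Alas2 2.39-fold and Slc4a1 3.22-fold (intervals -1.67 to -0.85 and -2.39 to -1.01 on the log2 scale).

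Further receptors for homing and adhesion were also lower. The chemokine receptor and adhesion list held 17 measured genes, 7 of them at least 1.5-fold lower, 10 between and none higher, and its median of -0.25 lay at percentile 0.05 of its random lists. Gpr15, which guides T cells to the colon, had 68 reads in the WT library and 9 in the KO library (14.6-fold lower, 7.26 to 33.3). The B cell follicle receptor Cxcr5 was 3.23-fold lower (2.89 to 3.63), the integrin chain Itgb1 3.12-fold lower (2.98 to 3.26) and Ccr6 2.92-fold lower (2.40 to 3.56). Exons of Gpr15 and Cxcr5 overlap exons of Cpox and Bcl9l on the opposite strand, and whether counting used strand is not given in the sources used here.

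The helper T cell genes split. Of 12 measured effector cytokines and helper factors, 2 were at least 1.5-fold higher, 5 lower and 5 between; the median was -0.10 (percentile 22.8) and the mean -0.51. The cytokine Ifng had 31 reads in the WT library and 18 in the KO library (3.33-fold lower, 1.81 to 6.32). Tbx21, which encodes T-bet, was 1.98-fold lower (1.45 to 2.71) and the IL-18 receptor chain Il18r1 1.88-fold lower (1.73 to 2.04). Cytokine genes under the expression floor were not measured.

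Genes of the resting state lay on the other side. All but 1 of the 18 resting T cell genes had a log2 ratio above 0, 4 were at least 1.5-fold higher and none was 1.5-fold lower, and the median of 0.34 lay at percentile 99.5. The insulin-like growth factor binding protein Igfbp4 was 1.88-fold higher (1.81 to 1.96), Klf2, a transcription factor that maintains T cell quiescence and egress, 1.70-fold (1.63 to 1.78), the IL-6 receptor Il6ra 1.52-fold and the transcriptional repressor Bach2 1.51-fold. After the GC correction Igfbp4 alone was still at least 1.5-fold higher, and Klf2, Il6ra and Bach2 had log2 ratios of 0.42, 0.52 and 0.53; total-count scaling also took Il6ra and Bach2 under 1.5-fold. The lymph node homing receptor Ccr7 was 1.39-fold higher (1.34 to 1.44).

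Immediate early and T cell receptor response genes were higher as a group. Of 22 measured genes 7 were at least 1.5-fold higher, 15 lay between and none was 1.5-fold lower. The median of 0.38 lay above all random lists. Log2 ratios were above 0 for 20 genes and below it for 2, Egr2 (-0.38) and Egr3 (-0.16). Cd69 and Cd5 differed little, at 0.19 and 0.14. The orphan nuclear receptor Nr4a1 was 1.91-fold higher (1.82 to 2.01), the AP-1 members Fos and Jun 1.82-fold and 1.73-fold, and the phosphatase Dusp2 1.76-fold. With the GC correction 5 genes of the list were at least 1.5-fold higher, 4 of them among the 7 called before. It took Dusp2 to a log2 ratio of 0.54, under 1.5-fold. The receptor complex and its kinases did not share this: all 20 TCR signalling machinery genes lay within 1.5-fold, with a median of 0.02 at percentile 14.6. Among the most different of them were Cd3g (log2 ratio -0.53), Cd28 (-0.41) and Malt1 (-0.39).

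Cholesterol synthesis genes were higher as a group. Of 18 genes 4 were at least 1.5-fold higher and none lower, 17 had a log2 ratio above 0, and the median of 0.38 lay above all random lists. The mevalonate pathway enzymes Mvd and Mvk were 1.87-fold (1.56 to 2.25) and 1.53-fold (1.25 to 1.87) higher. With the GC correction 5 genes of the list were at least 1.5-fold higher, 3 of them among the 4 called before. It took Mvk to a log2 ratio of 0.32, and with total-count scaling Mvk was at 0.53, both under 1.5-fold.

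**Figure D2:**
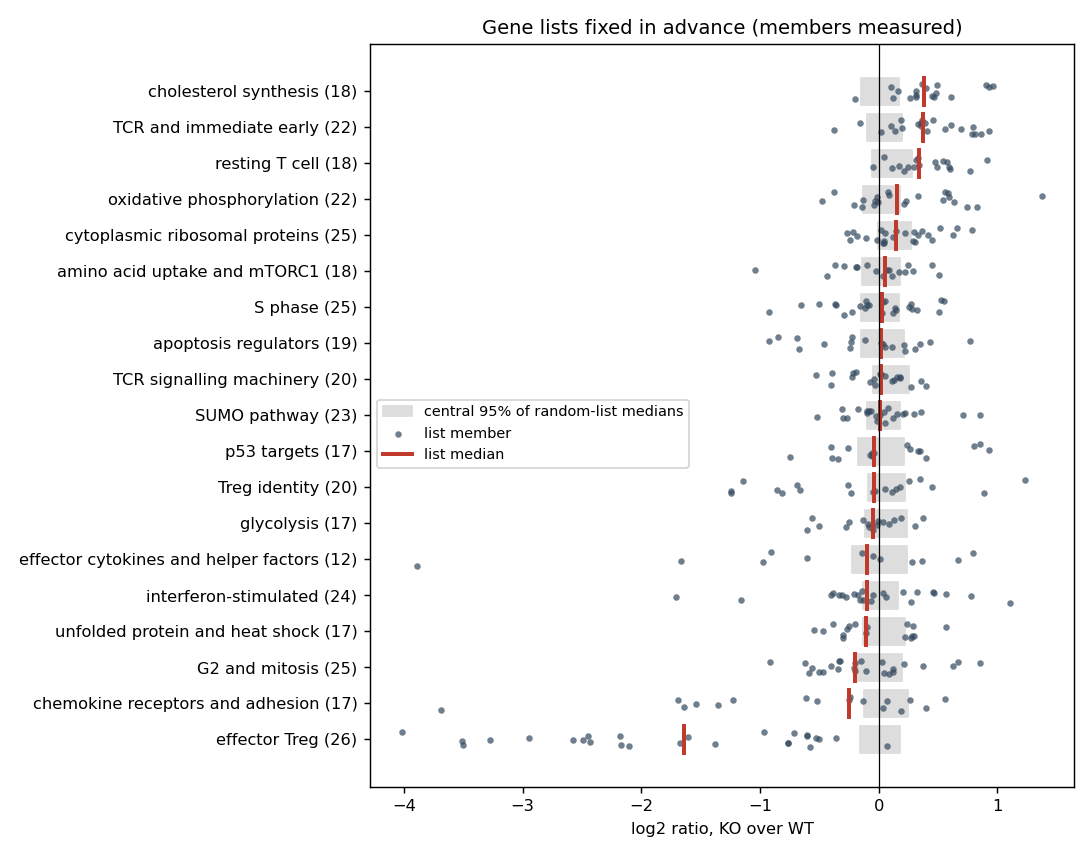
Log2 ratios of the KO to the WT library (horizontal axis) for the measured members of 19 gene lists (vertical axis, number of measured members in brackets). Each dot is a gene, the red bar the list median and the grey band the central 95% of the medians of 10000 random lists matched on mean expression. The medians of 5 lists lie outside their band: effector Treg (-1.64), chemokine receptors and adhesion (-0.25), resting T cell (0.34), TCR and immediate early (0.38) and cholesterol synthesis (0.38).

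The genes of Treg identity went both ways. Foxp3 had 8540 reads in the WT library and 30579 in the KO library, and Lrrc32, which encodes the surface protein GARP that presents latent TGF-β, had 2072 and 9443 (2.36-fold higher, 2.25 to 2.47). The high-affinity IL-2 receptor chain Il2ra was 1.36-fold higher (1.33 to 1.39). In contrast, the inhibitory receptors Lag3 and Ctla4 were 2.38-fold (2.11 to 2.68) and 1.61-fold (1.51 to 1.72) lower, the ecto-enzyme Nt5e (CD73) 2.37-fold lower, and the IL-35 subunit Ebi3, with 75 and 65 reads, 2.23-fold lower (1.58 to 3.16). Of the 20 genes 2 were at least 1.5-fold higher, 7 lower and 11 between; the median of -0.04 lay at percentile 9.84, while the mean was -0.18. With the GC correction Lrrc32 was at 0.90 on the log2 scale, under 2-fold, and Ctla4 at -0.46, under 1.5-fold. Exons of Foxp3 overlap those of Flicr on the same strand and of Ccdc22 and Ppp1r3f on the opposite strand.

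Proliferation genes differed little. Of 25 S phase genes 23 lay within 1.5-fold and 2 were lower, with a median of 0.03 at percentile 59.0; the ribonucleotide reductase subunit Rrm2 was 1.58-fold lower (1.34 to 1.85; under 1.5-fold with the GC correction, log2 ratio -0.50), and Mcm2 and Chaf1b had log2 ratios of 0.55 and 0.52. Of 25 G2 and mitosis genes 19 lay between, 3 were higher and 3 lower, with a median of -0.20 at percentile 3.005. The largest ratios there rested on few reads: Ttk had 27 in each library (1.93-fold lower, 1.09 to 3.43), Ube2c 20 and 71 (1.84-fold higher, 1.10 to 3.18), Cdk1 29 and 90 (1.61-fold higher) and Cenpf 49 and 147 (1.55-fold higher, and 0.55 on the log2 scale, under 1.5-fold, with total-count scaling). Of the 3 lower G2 and mitosis genes 1 was still lower with the GC correction.

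The SUMO pathway list did not stand apart. Of 23 genes 21 lay between, 2 were at least 1.5-fold higher and none lower, with a median of 0.01 at percentile 36.3. The modifier gene Sumo3 was 1.80-fold higher (1.69 to 1.93) and the PIAS-like ligase gene Zmiz1 1.64-fold higher (1.58 to 1.70). Exons of Sumo3 overlap those of Gm49325 on the same strand, so its count is less certain. With the GC correction Zmiz1 was at 0.45 on the log2 scale, under 1.5-fold.

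Stress and death pathways were mixed. Of 17 measured p53 targets 3 were higher, 1 lower and 13 between (median -0.04, mean 0.11, percentile 31.3); the pro-apoptotic Bbc3 was 1.92-fold higher (1.49 to 2.48), Phlda3 1.83-fold, Gadd45a 1.76-fold and Pmaip1 1.68-fold lower, and the cell cycle inhibitor Cdkn1a had 22 and 54 reads, a difference within its interval (1.27-fold, 0.760 to 2.19). With the GC correction Bbc3, Phlda3 and Pmaip1 had log2 ratios of 0.48, 0.46 and -0.54, all under 1.5-fold, so that 1 of the 3 higher calls and none of the lower was kept. Of 19 apoptosis regulators 1 was higher, 4 lower and 14 between (median 0.02, mean -0.10, percentile 48.2). Bak1 was 1.70-fold higher (log2 ratio 0.57 with the GC correction, under 1.5-fold), the death ligand Fasl 1.83-fold lower (1.22 to 2.73), and Bcl2a1b, which has near-identical copies that can share its reads, 1.90-fold lower. All 17 unfolded protein and heat shock genes lay between (median -0.11, percentile 4.24), with log2 ratios from -0.55 for Xbp1, through -0.47 for Hsp90aa1 and -0.38 for Hspd1, to 0.57 for Ddit3.

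Interferon-stimulated genes did not move as a group. Of 24 genes 2 were higher, 2 lower and 20 between, with a median of -0.10 at percentile 7.82. The chemokine Cxcl10 had 49 and 28 reads (3.38-fold lower, 2.09 to 5.59) and the guanylate-binding protein Gbp3 was 2.24-fold lower (2.05 to 2.46), while Xaf1 was 2.16-fold higher (1.85 to 2.53) and Ifi44 1.73-fold higher (1.19 to 2.55).

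Among metabolic lists other than cholesterol synthesis none stood apart. Of 17 glycolysis genes 1, the hypoxia-inducible transcription factor Hif1a, was lower (1.52-fold; log2 ratio -0.45 with the GC correction, under 1.5-fold) and 16 lay between (median -0.05, percentile 12.4); Hk2, Pfkp and Hk1 had log2 ratios of -0.56, -0.51 and 0.37, and Hk2 passed 1.5-fold with the GC correction (-0.63). Of 22 oxidative phosphorylation genes 5 were higher and 17 between (median 0.15, percentile 94.96), led by Ndufa1 (2.61-fold, 2.09 to 3.30), Ndufb3 (1.79-fold), Cox5a (1.68-fold) and Uqcrq (1.56-fold). The GC correction kept 3 of these 5 calls, with Ndufa1 at 0.96 on the log2 scale, under 2-fold, and Cox5a at 0.53, under 1.5-fold, and total-count scaling took Uqcrq to 0.56, under 1.5-fold. Of 18 amino acid uptake and mTORC1 genes 1 was lower and 17 between (median 0.06, mean -0.03, percentile 70.0); Asns had 21 and 19 reads (2.14-fold lower, 1.09 to 4.20; log2 ratio -0.91 with the GC correction and -0.88 with a pseudocount of 5, both under 2-fold), and Slc7a5, Shmt2 and Psat1 had log2 ratios of 0.51, 0.45 and -0.44. Of 25 cytoplasmic ribosomal proteins 3 were higher and 22 between (median 0.15, percentile 70.1), with Rplp1 1.73-fold, Rps19 1.58-fold, Rpl13a 1.55-fold and Rpl13 1.43-fold higher. With the GC correction Rplp1, Rpl13a and Rpl13 were at 0.12, 0.52 and 0.09 on the log2 scale, and Rps19 was the call that was kept. Of 18 germline genes only Brdt (23 and 63 reads) and Tuba3a (17 and 25) passed the expression floor, and neither was distinguishable from no difference at this depth (1.42-fold higher, 0.866 to 2.39, and 1.31-fold lower, 0.666 to 2.53).

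**Figure D3:**
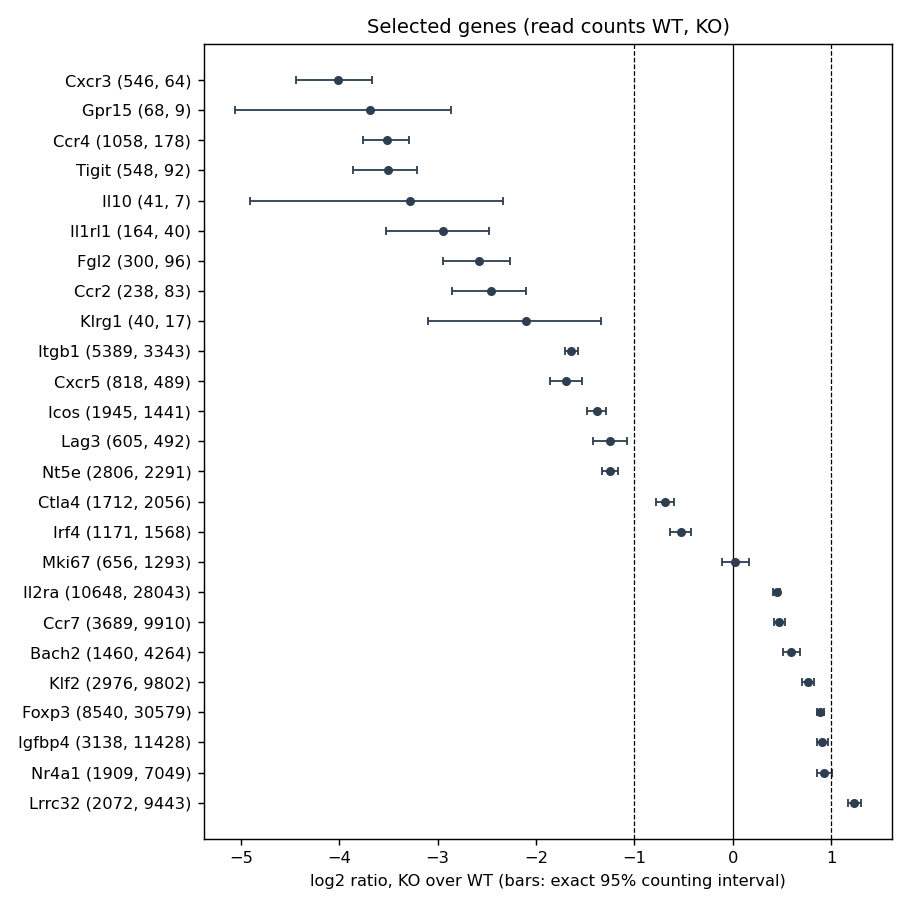
Log2 ratio of the KO to the WT library (horizontal axis) for 25 genes (vertical axis, WT and KO read counts in brackets). Points are the ratios with the pseudocount and bars the exact 95% counting intervals without it, which hold no spread between mice; dashed lines mark 2-fold. Effector receptors such as Cxcr3 (546 and 64 reads) lie at the lower end, and Foxp3 (8540 and 30579) and Lrrc32 (2072 and 9443) lie above 0.

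Over the whole table, the 12 genes with the lowest ratios among the 9051 with a mean of at least 100 reads included 6 of the effector Treg list, namely Cxcr3, Ccr4, Tigit, Il1rl1, Fgl2 and Ccr2. The other 6 were led by Gbp2b, an interferon-inducible guanylate-binding protein (chromosome 3, 142594847 to 142619179), with 308 reads in the WT library and 19 in the KO library (31.3-fold lower, 19.7 to 52.8). They also held the ribonuclease Rnase4 (182 and 24), the lipid enzyme Gdpd3 (725 and 134), the palmitoyltransferase Zdhhc2 (354 and 125), the serpin Serpina3g (759 and 311) and the enkephalin precursor Penk (326 and 135). Gbp2b and Serpina3g belong to families of near-identical genes, Rnase4 shares exons with Ang, and Zdhhc2, Gdpd3 and Penk overlap other genes on the opposite strand, so their counts are less certain.

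The 12 genes with the highest ratios held a single member of the fixed lists, Ndufa1. The 45S ribosomal RNA precursor Rn45s was 5.23-fold higher (5.13 to 5.34) and took 0.0843% of gene reads in the WT library (Clopper-Pearson interval 0.0826 to 0.0860) and 0.418% in the KO library (0.416 to 0.421). The libraries were made from mRNA captured on oligo-dT beads, and how much ribosomal RNA each preparation kept was not measured. The Rn45s ratio is therefore not a measure of its expression in the cells. The receptor phosphatase Ptprf followed with 93 and 647 reads (3.60-fold higher, 2.89 to 4.52), then the mitochondrial leucyl-tRNA synthetase Lars2 with 5075 and 34470 (3.51-fold; whether it shares reads with Rn45s was not checked, so its ratio is uncertain), and the transcription factor Sox4 (chromosome 13, 28948919 to 28953713) with 119 and 799 (3.47-fold, 2.86 to 4.25). The remaining genes were Zfp579, Pygm, Cybrd1, Erdr1, Map6, Mex3a and Rpl39, at 2.95-fold, 2.87-fold, 2.86-fold, 2.73-fold, 2.68-fold, 2.56-fold and 2.54-fold; Rpl39 has processed copies in the genome that can share its reads.

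Markers of other cells were present at levels from under the floor to near those of T cell genes. In TMM-scaled CPM (reads scaled to library size), Cd3e was at 735 in the WT and 833 in the KO library, Cd4 at 1939 and 2348, and Foxp3 at 713 and 1320. The highest levels in the B cell and macrophage lists were those of Cd74, the MHC class II invariant chain, at 508 and 537, and of Csf1r at 266 and 235. The B cell gene Cd79a was at 36.1 and 39.5, the macrophage gene Lyz2 at 123 and 126, and the NK and CD8 T cell gene Nkg7 at 11.9 and 4.88. None of the marker lists with at least 3 measured genes stood apart: B cell (12 genes, 2 lower, median -0.17, percentile 4.13), CD8 T cell (5, 2 lower, percentile 6.91), NK cell (4, 1 lower, percentile 14.3), monocyte and macrophage (14, 1 higher and 1 lower, median -0.13, percentile 10.7), neutrophil (3, 1 lower, median 0.00, percentile 49.6) and dendritic cell (6, none beyond 1.5-fold, median 0.28, percentile 93.5). The erythroid genes Alas2 and Slc4a1 had 115 and 93 reads, and 50 and 30. Fewer than 3 genes were measured for plasma cells (Igj with 59 and 75 reads, Mzb1 with 17 and 35), stromal and endothelial cells (Pecam1 with 3535 and 7511, Cdh5 with 22 and 36), thymocytes (Dntt with 13 and 35, Cd1d1 with 325 and 589) and gamma delta and innate-like T cells (Blk with 79 and 109). Mast cell and basophil genes summed to 20 and 43 reads and platelet genes to 12 and 9, all under the floor, and mitochondrially encoded genes were not analysed here. Xist had 3167 and 5923 reads, and the 4 Y-linked genes 1 read in the WT library and 0 in the KO library; a count of 0 allows up to 1.26e-05% of its gene reads.

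The counting interval excluded no difference for 170 of the 173 higher genes and for all 227 lower genes. It lay wholly beyond 2-fold for 35 and 105. These genes were picked for ratios of at least 2-fold, which favours an interval that excludes no difference. The interval also treats reads as independent molecules, which they are not, so it can be too narrow. Of 25 lists with a percentile, 5 stood apart, where random draws of unrelated genes would give 1.25. Members of a list can move together between any 2 pools, and the random lists were not matched on GC content. The 2 numbers are therefore no measure of significance. With 1 pool per group, differences between genotypes cannot be separated from differences between pools, sorts or library preparations.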

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

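The tests of the CD8 T and NK cell explanation, of effector cell number against expression per cell, and of a larger Treg share were chosen only after the results were seen, as were the GC content correction and the thinning.

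Reads counted outside annotated exons made up 6.81% of the KO library and 6.26% of the WT library, and reads shared between genes 1.57% and 1.53%. Both shares stood out because the KO value lay above the WT value by more than counting error, in entries that no comparison used.

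The lower effector Treg list in the KO library was set against 3 technical explanations. Removing the trend on GC content and transcript length left the list median at -1.62, still below all random lists drawn, so that trend does not account for it. Thinning the KO library to the WT depth left the median at -1.67, also below them. The ratios were already scaled to library size, so thinning mainly adds counting noise and cannot decide whether depth plays a part. For a loss of CD8 T or NK cells, abundant transcripts of these cells were compared with what the list lost. Ccl5, Nkg7, Gzma and Prf1 summed to 408 scaled reads in the WT library, 3.32% of the 12282 lost. Nkg7 (142 raw reads) and Prf1 (94) were the most abundant. The sum is small beside the loss. It uses the WT level of a few transcripts, not their difference, and need not match the loss of other genes. It therefore cannot exclude a part played by such cells. The CD4+ YFP+ gate is meant to exclude such cells, but markers of other cells were present in both libraries. Of the CD8 chains, Cd8b1 had 328 and 818 reads and Cd8a only 74 and 143. These counts do not settle whether CD8 T cells were in the pools. What stays open is whether the KO pool held fewer effector Treg cells or less of these transcripts per cell, and whether either follows the genotype: with 1 library per group these cannot be told apart. The hypothesis that effector Treg cells are fewer or less differentiated in the knockout is consistent with the list, and was not tested by any replicate.

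Foxp3 and Lrrc32 were higher in the KO library while 7 of the 20 Treg identity genes were at least 1.5-fold lower. Removing the GC trend left Foxp3 at 0.75 and Lrrc32 at 0.90 on the log2 scale, both above 1.5-fold. A larger share of Treg cells in the KO pool would, on its own, raise the other identity genes by about as much as Foxp3 (0.89). The median of the other 18 was -0.15 with a median absolute deviation of 0.45, which argues against a larger share as the whole cause. A larger share together with fewer effector Treg cells was not tested, and these values cannot exclude it. Reads from the genes whose exons overlap Foxp3, Flicr on the same strand and Ccdc22 and Ppp1r3f on the opposite strand, were not separated, and a biological difference in Foxp3 transcript level between the pools stays a hypothesis.

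The genes at least 2-fold higher in the KO library were rich in GC. Of 171 with a GC value, 86 (50.3%) were still at least 2-fold higher after the correction, against 200 of 226 lower genes (88.5%). The median log2 ratio of the 171 went from 1.19 to 1.00 (SD after correction 0.41), and that of the 85 whose call ended from 1.13 to 0.83, with 51 of them moving down by at least 0.3. The trend on GC content and length therefore may account for part of the size of these differences. How much of the rest is biological cannot be told apart with 1 library per group.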

How the results depend on the processing

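The GC and length correction and the thinning were chosen only after the data were seen; the other settings were planned. No paired analysis was possible because each group has 1 library. The 5 lists that stood apart did so under all settings run, with medians of the effector Treg list from -1.72 to -1.18. Counts of genes followed the floor and the threshold by construction. Against 173 higher and 227 lower genes, no floor gave 1027 and 1186, a floor 5 times as high 62 and 95, a 1.5-fold threshold 810 and 600, a 4-fold threshold 8 and 44, and an interval wholly beyond 2-fold 35 and 105. Removing the GC trend gave 99 higher genes. The higher floor left 13 effector Treg genes at least 1.5-fold lower in place of 21, with fewer genes measured. Some lists stood apart only under 1 or 2 settings: Treg identity by its mean (-0.18) and with the GC trend removed (-0.14), effector cytokines and helper factors without a floor (-0.32) and by the mean (-0.51), G2 and mitosis without matching (-0.20), glycolysis with the GC trend removed (-0.16), oxidative phosphorylation by the mean (0.24), and unfolded protein and heat shock after thinning (-0.15); the cause was not tested. Of 493 recomputed ratios of single named genes, 491 kept their sign and 435 stayed inside the counting interval; the other 2 were of Mki67, near 0 throughout, at -0.05 with total-count scaling and -0.02 with the GC trend removed. Of 74 named genes with a GC value that differed by at least 1.5-fold, 16 fell short of it with the GC trend removed; 6 of 76 did so with total-count scaling, and none with DESeq2 size factors or either pseudocount. Medians near 0 (S phase, SUMO pathway, TCR signalling machinery, amino acid uptake and mTORC1, apoptosis regulators) changed sign with total-count scaling, and that of p53 targets without a floor (0.10), so no direction is given for them. Depth limits genes such as Il10, Klrg1, Gpr15 and Ifng, with few reads in both libraries, to a direction and a rough size.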

Other observations

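The gene groups here were put together only after the values were seen, so their percentiles describe a choice made on these data. Receptors of the IL-1 family were lower as a group in the KO library. Of 6 measured, 4 were at least 1.5-fold lower and none higher, with a median of -1.27 (-1.18 with the GC trend removed) below all random lists. The IL-33 receptor Il1rl1 was at -2.95, the decoy receptor Il1r2 (90 and 30 reads) at -2.49, and the IL-18 receptor chains Il18rap (136 and 84) and Il18r1 at -1.63 and -0.91. Receptors that signal with the common γ chain, and the chain itself, differed from this: of 8 measured, 7 lay within 1.5-fold and the median was 0.03 (-0.05 with total-count scaling), with Il9r (91 and 50 reads) the exception at -1.79.

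Genes of the Naip and Nlrp1 inflammasome sensors, grouped with Casp1 and Nlrc4, were all lower, 6 of 6, with a median of -1.55. Naip2 had 346 and 246 reads (-1.44), Casp1 135 and 101 (-1.36) and Nlrp1b 48 and 27 (-1.73); Naip2, Naip5 and Naip6 are near-identical neighbours, so their counts are uncertain. Removing the GC trend left the median of the group at -1.49. Of 10 guanylate-binding protein genes 3 were lower, the median was -0.36, and Gbp2b stood far from the rest; with the GC trend removed the median was -0.23, and Gbp10 went from -0.68 to -0.52, which left 2 lower. Of 5 measured S100 genes 3 were lower and 1 higher, with S100a11 (448 and 343 reads) at -1.33. Removing the GC trend took the higher one, S100a13, from 0.82 to 0.49, under 1.5-fold, and S100a10 from -0.47 to -0.71, past it. The 8 measured Gimap genes all lay within 1.5-fold, and 19 of 22 MHC genes did.

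Subunits of the respiratory chain that no fixed list holds had higher medians before the trend on GC content and length was removed than after. The tenth of expressed genes with the shortest transcripts had a median log2 ratio of 0.16 as scaled. GC content and length were corrected together, so the part of each in these shifts was not separated. The median of 7 cytochrome oxidase subunits was 0.55 and became 0.29, that of 10 Ndufa subunits of complex I went from 0.27 to 0.01, and that of 51 ribosomal protein genes from 0.27 to 0.09.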
